A study of Mus musculus with 16 samples.

How the data were processed

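Hearts were taken from wild-type pups and from pups with a heart-conditional knockout of Tfr1, on a mixed 129 and C57BL6 background, at postnatal day 5 or postnatal day 10. Per the labels' protocols, hearts were snap frozen, RNA was isolated with a Qiagen RNeasy kit, targets were made with a MessageAmp Premier kit and biotin, and a core facility hybridised and scanned Affymetrix arrays. The 16 arrays formed 4 groups of 4, by genotype and age, each array carrying its own animal number in its label. The labels do not state sex, litter, hybridisation batch or scan date.

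The deposited values are on a log2 scale, with RMA and Partek 6.5 named in the submitters' processing notes and no role given for either. The table held 45101 probe sets. All 8 arrays of one age shared a value distribution, with a median of 6.30 at day 5 and 5.03 at day 10, so the median of the day 5 arrays lay 1.27 higher, and the spread of all values was 2.16 at day 5 and 2.32 at day 10 (SD). The 2 ages were therefore taken as normalised apart, and levels are not on 1 scale between them. For this reason the planned comparison of day 10 with day 5 within wild-type hearts, and its gene lists, was not run: age and processing cannot be told apart there. The comparisons of knockout with wild type lie within 1 age. The difference between those 2 changes was kept, with the limit that a unit of log2 need not mean the same at both ages.

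Gene names came from the array's annotation: 34945 probe sets outside the controls named 1 gene, 932 of the probe sets named several and 9211 had no symbol listed. Names were checked against a mouse reference gene table (GRCm38.p6), which held the Entrez ID of 34741 of them; no coordinates were used. Each of 18193 genes was represented by the probe set with the highest mean over all 16 arrays, control probe sets were left out, and no dim probe set was removed. The number of arrays, 4 per group, limits the precision. Group differences were fitted with limma 3.58.1 (R 4.3.3), as 4 group means over all 16 arrays with 1 shared spread per gene, moderated by eBayes, and p-values were adjusted by Benjamini-Hochberg over all genes; a gene was called at an adjusted p under 0.05. All adjusted p-values of single genes come from that model unless another is named, and a value after ± is an SD over 4 arrays or, where stated, the model's SE.

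The spread within groups was smaller at day 5 than at day 10 (median residual SD 0.0869 and 0.131), so a shared spread favours calls at day 10 and disfavours them at day 5. The test was run on simulated values with the measured means and each age's own spread, where 200 of 18193 genes were changed. For the day 5 comparison it recovered 76.1% of genes changed by 0.5, 97.0% of those changed by 1 and every gene changed by 2 on the log2 scale, with 10 false calls among 192. For the day 10 comparison the shares were 82.1%, 94.0% and every gene, but 115 of 299 calls were false, against 16 of 184 when the 8 arrays of that age were fitted alone. In a second simulation, added after the first was seen, with each gene's spread moderated within its age, 99 of 289 and 17 of 190 calls were false. Counts from the 8 arrays alone are therefore given with the day 10 counts of genes and of list members over all genes. For the difference between ages 47.8%, 91.0% and 98.5% were recovered, with 18 false calls among 176.

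Before the data were examined, 40 gene lists were written, covering iron handling, mitochondria, metabolism, stress programmes, heart maturation and markers of other cell types and tissues, and 767 of their 832 entries were measured. Lists were tested with camera at its preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 40 lists, and again with an estimated correlation and with fry. In a simulated day 10 data set with 1 moved list, targets of hypoxia-inducible factor, camera called that list and 2 others. The noise was drawn for each gene independently, so this says nothing on correlation between genes. The moved list shares members with others, such as Slc2a1 with glycolysis and Egln3 with iron-dependent oxygenases, so the 2 others may hold moved genes. Results of lists that share members are not independent. Genes named in the text were chosen by a rule fixed at the same time: Tfrc; for each age, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap; for the difference between ages, 5 and 5 by adjusted p under 0.05 alone; and, in each list described, up to 4 called members with the smallest p, or up to 2 uncalled members, as values, where fewer than 2 were called. Gene models without a proper symbol were passed over.

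Alternatives fixed before the data were examined covered normalisation across arrays, a filter on dim genes, the choice of probe set, eBayes with trend and robust, array weights, the mean of the measured Y-linked genes as a covariate, animals with neighbouring tag numbers as a random block, the 8 arrays of 1 age alone, stricter thresholds and each array left out. Covariates for brown fat and airway markers, scaling each age to a common SD, leaving out the knockout and wild-type replicates 3 of day 10 together, and lists tested on 8 arrays were added after seeing the data. Replicate numbers follow accession order and were not used to pair samples.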

Results

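Gene expression was measured in the hearts of wild-type mice and of mice labelled as heart-conditional knockouts of Tfr1, at postnatal days 5 and 10. Tfr1, encoded by Tfrc, is the receptor through which cells take up transferrin-bound iron. Each of the 4 groups held 4 arrays, 1 animal each. Within an age the array medians spanned 0.0394 at day 5 and 0.0471 at day 10 on the log2 scale. Mean correlation of an array with the rest of its group was 0.997 or more at day 5, between 0.991 and 0.996 for 7 arrays at day 10, and 0.985 for knockout replicate 3 at day 10.

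The targeted gene was read first, from 6 probe sets. The probe set with the highest signal measured 11.92 ± 0.38 in wild-type and 12.93 ± 0.07 in knockout hearts at day 5 (SD, n = 4 each), so Tfrc signal rose by 1.01 (SE 0.17, limma adjusted p = 0.0231), with all 4 knockout values above all 4 wild-type values. At day 10 the same probe set measured 11.30 ± 0.17 and 11.68 ± 0.33, a difference of 0.38 that did not pass the test (limma adjusted p = 0.137); without knockout replicate 3 it was 0.54 and did (limma adjusted p = 0.0162). The mean of the gene's probe sets differed by 0.088 at day 10 (limma adjusted p = 0.754), and the 4 probe sets other than this and the 5′ control differed by -0.066, -0.046, 0.028 and 0.10, none called. The control probe set for the 5′ part of the transcript went the other way. It fell by 1.61, from 6.29 ± 0.09 to 4.68 ± 0.14, at day 5 and by 0.46, from 2.95 ± 0.12 to 2.49 ± 0.10, at day 10, without overlap between genotypes at either age. Limma's adjusted p over 45101 probe sets was 3.67e-08 and 0.00119. Both knockout means lay under the median of all values of their age, 6.30 and 5.03. Signal that low was not shown to be above background, so the sizes of these falls are uncertain. The control probe sets for the middle and 3′ parts differed by 0.97 and 0.57 at day 5, neither passing the test (limma adjusted p = 0.0517 and 0.165). Of the 2 other probe sets, 1 rose by 0.63 at day 5 (limma adjusted p = 0.0380) and 1 differed by 1.08 without a call (limma adjusted p = 0.199). Beta-actin 3′ minus 5′ signal, a sign of RNA quality, lay between 1.005 and 1.07 in wild-type and between 0.93 and 1.20 in knockout arrays at day 5. The labels do not say which part of Tfrc was deleted, so a probe set outside it checks nothing about the label; the 5′ probe set was lower in all 8 knockout arrays than in any wild-type array of the same age. The day 5 call of the probe set with the highest signal was lost when any 1 of 6 arrays was left out, with limma adjusted p between 0.0864 and 0.108, and kept without wild-type replicate 3 or knockout replicate 1. With the Y-linked mean as a covariate the change was 1.13 and not called (limma adjusted p = 0.0888). That mean partly followed genotype at day 5.

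**Figure D1:**
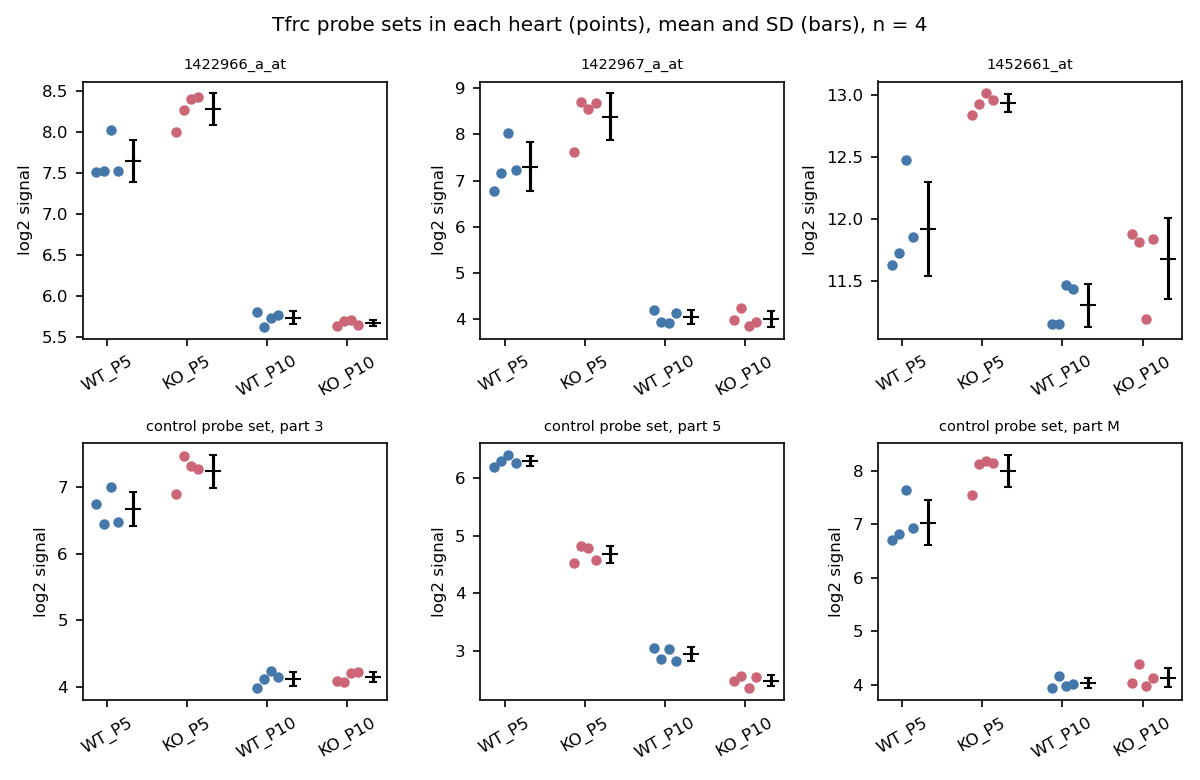
Log2 signal of the 6 Tfrc probe sets in each array (points; wild type blue, knockout red), with mean and SD of 4 arrays beside them; each panel has its own axis, which does not start at 0, and levels of the 2 ages are not on 1 scale. The 5′ control probe set lies lower in knockout than in wild-type arrays at both ages, while the probe set with the highest signal (top right panel) lies higher in knockout arrays at day 5.

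The first comparison asked how knockout hearts differed from wild-type hearts at day 5. Lists of the response to low oxygen and of glycolysis were higher in the knockout, while of the 19 genes called lower 1, Nqo1, was in a list. Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factor, rose 2.16-fold, from 9.54 ± 0.18 to 10.66 ± 0.33. Ak4, a mitochondrial adenylate kinase, rose by 0.99 and Bnip3, a mitophagy receptor, by 0.90. Cabcoco1 fell by 1.73, and Iigp1, an interferon-inducible GTPase, fell by 1.58.

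Of 18193 genes, 27 were called at day 5, 8 higher and 19 lower in the knockout, and 847 had an unadjusted p under 0.05. The called rises were completed by Tfrc (1.01), Pdxp, a pyridoxal phosphatase (0.69), the cytokine Mif (0.60), glyoxylate reductase Grhpr (0.53) and the glycolytic enzyme Aldoa (0.36). The further falls chosen by size were Asb5 (-1.08), Dhdh (-0.89), the endocytic receptor Cubn (-0.86), Gadl1 (-0.84), the folate enzyme Ftcd (-0.84), Pcbd1 (-0.76), the actin-capping tropomodulin Tmod4 (-0.75) and cardiotrophin Ctf1 (-0.57). Limma's adjusted p for these named genes ran from 0.000109 for Ak4 to 0.0271 for Mif, and in each the 4 knockout arrays lay on 1 side of the 4 wild-type arrays.

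Camera placed 9 of the 40 lists past the threshold at day 5, 6 higher and 3 lower. Glycolysis and glucose uptake rose as a list, with a median of 0.24: 1 of 22 measured members was called over all genes, and 9 rose when adjusted over the list alone (camera adjusted p = 3.18e-14, and adjusted p = 0.00413 with an estimated correlation). Its glucose transporter Slc2a1 measured 0.79 and its phosphofructokinase Pfkl 0.68 above wild type, neither called (limma adjusted p = 0.0648 and 0.149). With the 8 day 5 arrays alone Slc2a1 was called and Pfkl was not (limma adjusted p = 0.00906 and 0.0547). Targets of hypoxia-inducible factor rose with a median of 0.23, through 2 of 25 members, Egln3 and Bnip3, over all genes and 13 adjusted over the list alone (camera adjusted p = 5.66e-18, and adjusted p = 0.0266 with an estimated correlation). Endothelial markers rose with a median of 0.14; all 15 were positive, none was called over all genes and 4 were called adjusted over the list alone (camera adjusted p = 3.86e-11, and adjusted p = 0.0266 with an estimated correlation). Emcn, an endothelial sialomucin, and the endothelial co-receptor Eng differed by 0.32 and 0.16, not called.

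The other 6 list calls at day 5 were lost with an estimated correlation and with fry. Immediate early genes were higher with a median of 0.32 (adjusted p = 0.235 with an estimated correlation), 18 of 19 being positive and none called, Junb at 0.79 and Ccn1 at 0.69. Iron-dependent oxygenases and mitochondrial chaperones were higher by medians of 0.050 and 0.055 (adjusted p = 0.171 and 0.430 with an estimated correlation); Egln3 was the member called among the oxygenases, and the collagen prolyl hydroxylase P4ha1 differed by 0.39 without a call. Mature cardiomyocyte genes, fibroblast markers and extracellular matrix genes were lower by medians of -0.052, -0.10 and -0.093 (adjusted p = 0.576, 0.212 and 0.576 with an estimated correlation). No member of these 3 lists was called over all genes; creatine kinase Ckmt2 measured -0.60, the sodium-calcium exchanger Slc8a1 -0.20, and the fibroblast genes Mfap5 and Tcf21 -0.39 and -0.18 (Tcf21 -0.090 without knockout replicate 2). Of 27 measured iron genes, Tfrc was the 1 called; Fbxl5, which directs iron regulatory protein 2 to degradation, and the mitochondrial iron importer Slc25a28 measured -0.32 and -0.22 (limma adjusted p = 0.0914 and 0.544). Without knockout replicate 1 limma called Pfkl, Junb, P4ha1 and Fbxl5 too (0.81, 1.05, 0.48 and -0.37). The respiratory complexes, tricarboxylic acid cycle and fatty acid oxidation held no called gene at day 5. With the 8 day 5 arrays alone limma called 63 genes, 14 higher and 49 lower, and with the Y-linked mean as a covariate it called 2. Leaving out 1 array gave between 10 and 37 calls, with 7 of the 8 arrays moving the count by more than 1.5 times: 14 to 16 calls without a wild-type array, and 11, 14 and 10 without knockout replicates 2, 3 and 4. Each of these 7 arrays, left out, ended at least 1 of the calls of Tfrc, Bnip3, Mif, Aldoa, Asb5, Cubn, Gadl1, Ftcd and Nqo1.

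At day 10 the question was the same, and the difference between genotypes was broad. Knockout hearts had higher levels of genes of the integrated stress response. Lists of low-oxygen targets, of glycolysis and of the fetal and stress programme of the heart were higher, and that of mature cardiomyocyte genes lower, by camera's preset correlation but not by an estimated one. Fry, which does not set a list against the other genes, called each of these lists too (fry adjusted p = 4.28e-06, 4.28e-06, 0.00338 and 0.000464). Nmrk2, a muscle kinase on the route from nicotinamide riboside to NAD, rose 35.5-fold, from 7.19 ± 0.49 to 12.33 ± 0.23 (SD, n = 4 each). Aqp4, a water channel, fell by 3.86, from 7.92 ± 0.20 to 4.07 ± 1.42. That knockout mean lies under the day 10 median of 5.03 and under 5.17, the 40th percentile of the values of both ages pooled. Signal that low was not shown to be above background, so the size of the fall is uncertain.

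Limma called 3753 genes at day 10, 20.6% of those tested, 1767 higher and 1986 lower; 254 of them differed by at least 1 on the log2 scale, 79 higher and 175 lower. With the 8 day 10 arrays alone it called 1570 genes, 776 higher and 794 lower, 1561 of them among the 3753. In simulated day 10 values with 200 of 18193 genes changed, 115 of 299 calls from the shared spread were false against 16 of 184 from the 8 arrays. Far more genes were called in the measured data, so these false shares cannot be carried over to the 3753 or the 1570. Among called genes whose groups did not overlap, the largest rises after Nmrk2 were Plcxd2 (2.97), the collagen hydroxylase P3h2 (2.26), the mitochondrial folate enzyme Mthfd2 (2.24), the matricellular genes Ccn1 (2.06) and Ccn2 (1.90), Slc2a1 (2.01), Egln3 (1.90), the collagen Col8a1 (1.85) and Ak4 (1.83). The largest falls after Aqp4 were Cabcoco1 (-3.60), Asb15 (-2.94), the splicing regulator Rbfox1 (-2.85), Iigp1 (-2.60), Tmod4 (-2.48), the potassium channel Kcnd2 (-2.45), the phospholipase Pla2g5 (-2.43), Lrtm1 (-2.36) and Gpr22 (-2.28). Limma's adjusted p for these 20 genes was between 2.58e-09 and 0.00206. The knockout means of Cabcoco1, Tmod4, Pla2g5 and Gpr22, like that of Aqp4, lay under 5.17, so the sizes and ranks of these falls are uncertain. Knockout replicate 3 measured 3.47 for Asb15, 3.98 for Rbfox1 and 4.04 for Kcnd2. The other knockout arrays measured 6.38 to 7.42, 5.34 to 6.61 and 6.42 to 7.10, in that order. The sizes and ranks of these falls therefore rest in part on replicate 3.

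Fry called 18 of the 40 lists at day 10, 9 higher and 9 lower. Camera placed 19 of the 40 lists past the threshold at day 10, 10 higher and 9 lower, and 1 of these with an estimated correlation. That list was the integrated stress response, targets of the transcription factor ATF4: 21 of 32 measured members rose and 2 fell (22 and 2 adjusted over the list alone; 17 and 1 with the 8 arrays), with a median of 0.56 (camera adjusted p = 1.79e-12, and adjusted p = 0.0442 with an estimated correlation). Among them the pseudokinase Trib3 rose by 1.20, the glutathione-degrading enzyme Chac1 by 1.41, Atf4 itself by 0.88 and the alanyl-tRNA synthetase Aars by 0.73. Targets of hypoxia-inducible factor rose in 17 and fell in 1 of 25 (18 and 1 adjusted over the list alone; 15 and 1 with the 8 arrays), with a median of 0.44 (adjusted p = 0.0774 with an estimated correlation). The oxidoreductase Ero1a rose by 0.83 and Bnip3 by 1.51. Glycolysis and glucose uptake rose in 11 and fell in 2 of 22 (12 and 3 adjusted over the list alone; 11 and 0 with the 8 arrays), with a median of 0.38 (adjusted p = 0.0774 with an estimated correlation). Phosphofructokinase Pfkp rose by 1.38, hexokinase Hk2 by 0.88 and phosphoglycerate kinase Pgk1 by 0.52.

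Fetal and stress genes of the heart rose in 11 and fell in 2 of 18 (the same counts adjusted over the list alone; 10 and 1 with the 8 arrays), with a median of 0.77 (adjusted p = 0.311 with an estimated correlation). Nppb, which encodes the B-type natriuretic peptide, rose by 1.38 and Bex1 by 1.38. Immediate early genes rose in 7 and fell in 0 of 19 (9 and 0 adjusted over the list alone; 4 and 0 with the 8 arrays; adjusted p = 0.360 with an estimated correlation), Myc by 1.59. Targets of p53 and apoptosis genes rose in 6 and fell in 1 of 17 (the same counts adjusted over the list alone; 5 and 1 with the 8 arrays; adjusted p = 0.276 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 1.79 and the survival gene Bcl2 by 0.92, while the death gene Bcl2l11 fell by 0.87. Mitochondrial chaperones and proteases rose in 7 and fell in 2 of 15 (8 and 2 adjusted over the list alone; 5 and 0 with the 8 arrays; adjusted p = 0.311 with an estimated correlation), the matrix protease Lonp1 by 0.70. Endothelial markers rose in 9 and fell in 0 of 15 (11 and 0 adjusted over the list alone; 8 and 0 with the 8 arrays), with a median of 0.36 (adjusted p = 0.0774 with an estimated correlation), Flt1 by 0.56 and Egfl7 by 0.50.

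Mature cardiomyocyte genes fell in 13 and rose in 1 of 27 (15 and 2 adjusted over the list alone; 6 and 0 with the 8 arrays), with a median of -0.20 (camera adjusted p = 1.01e-05, and adjusted p = 0.276 with an estimated correlation). The calcium release channel Ryr2 fell by 0.65, Ckmt2 by 0.98 and phospholamban, Pln, by 0.51. In 5 lists of mitochondrial energy metabolism some members fell by small amounts, while complex IV moved both ways, 4 of 15 lower and 2 higher. The tricarboxylic acid cycle list had 11 of 21 members lower and none higher (14 lower adjusted over the list alone), complex I 6 of 33 (6), complexes II and III 6 of 14 (8), ATP synthase 7 of 16 (12) and fatty acid oxidation 8 of 24 (9 lower and 1 higher). Camera called all 5 lists, with medians between -0.10 and -0.19, and in each the call was lost with an estimated correlation (adjusted p = 0.494, 0.625, 0.485, 0.485 and 0.654 with an estimated correlation, in that order). Fry called the lists of the tricarboxylic acid cycle, complexes II and III and ATP synthase lower (fry adjusted p = 0.0138, 0.00457 and 0.00496). It did not call those of complex I and fatty acid oxidation (fry adjusted p = 0.05 and 0.1665). Citrate synthase Cs fell by 0.25, pyruvate dehydrogenase Pdha1 by 0.24, the complex I and III subunits Ndufb2 and Uqcr11 by 0.26 and 0.26, the fatty acid enzymes Hadh and Acadm by 0.36 and 0.43 (Acadm -0.28 without knockout replicate 3), and Atp5e by 0.39. With the 8 day 10 arrays alone, 1 gene of these 5 lists was called, in ATP synthase. Of 18 regulators of mitochondrial biogenesis 6 fell and none rose (7 and 1 adjusted over the list alone; 3 and 0 with the 8 arrays), a list that camera did not call (adjusted p = 0.0899); the nuclear receptor Ppara fell by 1.001 and the coactivator Ppargc1a by 0.75.

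Iron and heme genes moved in both directions. Of 27 measured iron genes 8 fell and 2 rose (11 and 4 adjusted over the list alone; 4 and 0 with the 8 arrays), and camera did not call the list (adjusted p = 0.0684). Fry did call the iron list, as lower (fry adjusted p = 0.000942). Hamp, which encodes the iron hormone hepcidin, fell by 1.88. Its knockout mean of 5.05 lay under the 5.17 pooled over both ages but near the day 10 median of 5.03. Its regulator hemojuvelin, Hjv, fell by 1.62, the ferritin receptor Scara5 by 1.01 and Fbxl5 by 0.41. Of 16 heme genes 6 fell and 1 rose (8 and 2 adjusted over the list alone; 2 and 0 with the 8 arrays), with a median of -0.24 (camera adjusted p = 0.0286, and adjusted p = 0.625 with an estimated correlation). Urod and ferrochelatase, Fech, enzymes of heme synthesis, fell by 0.53 and 0.48. In iron-sulfur cluster assembly 6 of 23 rose and 6 fell (6 and 7 adjusted over the list alone; 4 and 0 with the 8 arrays), Gfer rising by 0.77 and Nubp1 by 0.59.

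Markers of other tissues differed between arrays at day 10, beside all of these groups. Of 12 adipose genes 6 fell and none rose in the knockout (7 lower adjusted over the list alone; 0 with the 8 arrays; adjusted p = 0.485 with an estimated correlation). Ucp1, the brown fat uncoupling protein, measured 11.23 ± 0.41 in wild-type and 9.54 ± 1.23 in knockout arrays, and Adipoq fell by 1.26. The mean of 4 brown fat markers was 8.004 to 9.09 in wild-type arrays and 6.62, 8.53, 6.87 and 7.09 in knockout replicates 1 to 4, so replicate 2 was not lower. The airway gene Scgb1a1 measured 10.53 to 12.75 in wild-type arrays and 2.70, 12.72, 9.94 and 3.82 in knockout replicates 1 to 4, a mean difference of -4.20 that was not called (limma adjusted p = 0.0651) but was -6.01 and called without knockout replicate 2, -5.09 and called without replicate 3 and -2.67 without replicate 1, and Scgb3a2 fell by 3.60 (limma adjusted p = 0.0497), a call lost without any 1 of 6 arrays, all but knockout replicates 2 and 3. The lung surfactant gene Sftpc, named after its values were seen, measured 11.32 in wild-type replicate 3 and between 5.05 and 5.43 in the 7 other day 10 arrays. Albumin, Alb, a liver gene, measured 9.29 and 8.54 in knockout replicates 2 and 3 and at most 6.17 elsewhere at day 10, and rose by 1.85, a call lost without any 1 of 6 arrays, all but knockout replicates 1 and 4, and a change of 1.20 without knockout replicate 2. With the mean of 4 brown fat markers as a covariate limma called 855 genes at day 10, 422 higher and 433 lower. The named calls of Cs, Pdha1, Hadh, Acadm, Uqcr11, Ndufb2, Fech, Dcn, Ucp1, Adipoq, Scgb3a2, Alb, Smtn and Kcnj3 did not hold with the 8 arrays alone, where 56 of the 70 called genes named here for day 10 held.

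**Figure D2:**
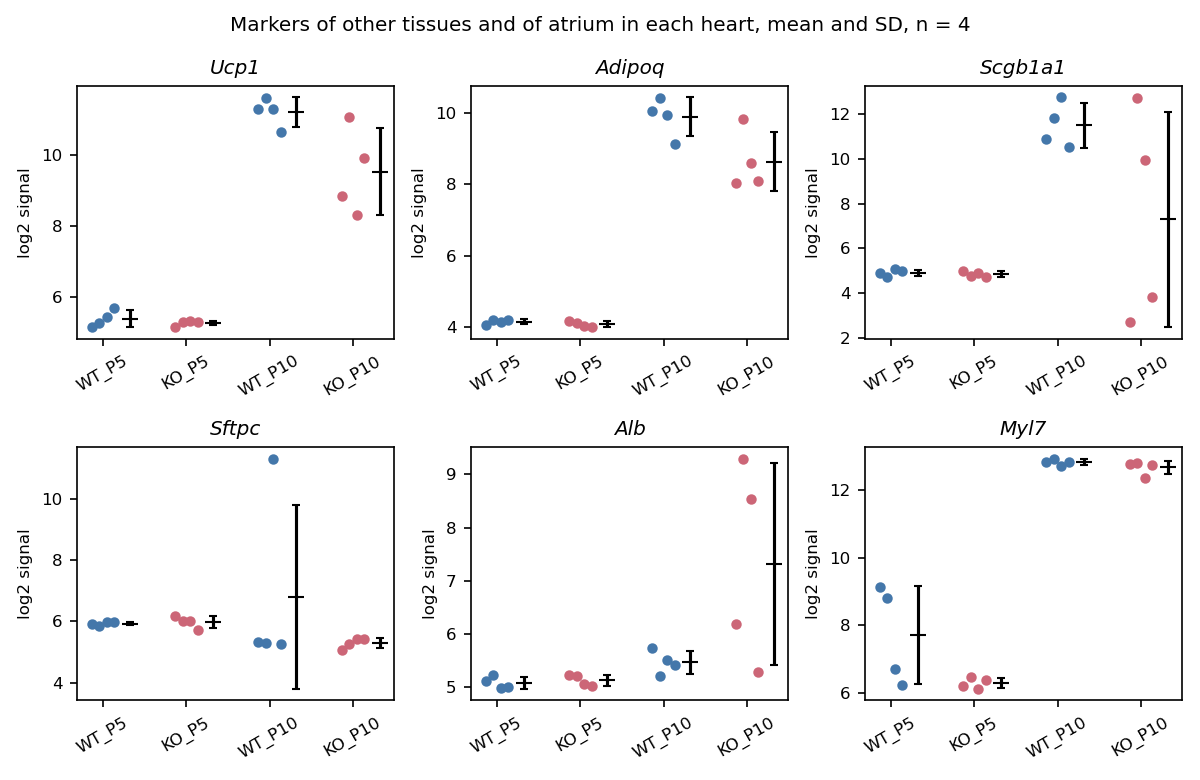
Log2 signal of markers of brown fat (Ucp1, Adipoq), airway (Scgb1a1), lung (Sftpc), liver (Alb) and atrium (Myl7) in each array (points; wild type blue, knockout red), with mean and SD of 4 arrays; axes do not start at 0 and levels of the 2 ages are not on 1 scale. Scgb1a1 splits the knockout arrays of day 10, with 2.70 and 3.82 in replicates 1 and 4, and Sftpc is at 11.32 in 1 wild-type array.

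The third comparison asked whether the knockout effect itself differed between the ages. Limma called 494 genes for the difference between the changes, 289 with a more positive and 205 with a more negative change at day 10, and all 494 differences had the sign of the day 10 change. Of the 494, 492 were called at day 10 and 9 at day 5. The largest positive differences were Nmrk2 (4.13), Plcxd2 (2.63), the skeletal alpha-actin Acta1 (2.50), P3h2 (2.19) and Mthfd2 (2.14), with limma adjusted p between 0.000246 and 0.0169. Acta1 differed by -0.88 at day 5, not called, and rose by 1.62 at day 10. The largest negative differences were Aqp4 (-3.03), Lrtm1 (-1.96), Cabcoco1 (-1.86), Hamp (-1.85) and Gpr22 (-1.78), with limma adjusted p between 0.00173 and 0.0408. Hamp lay at 4.54 to 5.18 in all 8 day 5 arrays, where a fall could not be seen, so its difference restates the day 10 fall, and the day 10 knockout means of Aqp4, Cabcoco1 and Gpr22 were under 5.17. The call of Aqp4 was lost without any 1 of 12 arrays, all but knockout replicate 2 of day 5 and knockout replicates 1, 2 and 3 of day 10.

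Camera placed 16 of 40 lists past the threshold for this difference, 8 higher and 8 lower. Fry called the integrated stress response, fetal and stress genes and hypoxia-inducible factor targets higher (fry adjusted p = 0.000203, 0.0323 and 0.0350). It called the iron list lower (fry adjusted p = 0.0350) and no other list. In the integrated stress response 15 of 32 members had a larger positive change at day 10 and none a more negative one (19 and 1 adjusted over the list alone; camera adjusted p = 4.87e-14, and adjusted p = 0.0281 with an estimated correlation), Chac1 by 1.56 and Trib3 by 1.07. Glycolysis and glucose uptake had 2 of 22 called, both positive (4 adjusted over the list alone; adjusted p = 0.464 with an estimated correlation). Fetal and stress genes had 3 of 18 called (11 positive and 1 negative adjusted over the list alone; adjusted p = 0.351 with an estimated correlation). Targets of hypoxia-inducible factor had 3 of 25 called, all positive (9 adjusted over the list alone; adjusted p = 0.395 with an estimated correlation), Slc2a1 by 1.22. Cdkn1a differed by 1.65, Gfer by 0.75, Ppara by -1.08 and Ryr2 by -0.57. The tricarboxylic acid cycle and complex I lists were more negative at day 10, with medians of -0.21 and -0.13 and no single gene called (2 and 0 adjusted over the list alone; adjusted p = 0.550 and 0.568 with an estimated correlation). Because the ages were normalised apart, this difference rests on a unit that may not be equal at both. With each age scaled to a common SD limma called 415 genes. Markers of other tissues and of atrium also differed by age, although the day 10 median was the lower. Ucp1 measured 5.16 to 5.70 at day 5 and 8.32 to 11.63 at day 10, and Myl7 6.14 to 9.12 and 12.35 to 12.90. What the samples held at each age cannot be told apart from age in this difference. Leaving out 1 array gave between 246 and 1021 calls, and the brown fat covariate gave 41. In 10 cases the count moved by more than 1.5 times. It was 276 and 281 without wild-type replicates 1 and 2 of day 5, 273 and 246 without knockout replicates 1 and 3 of day 5, and 322 and 326 without wild-type replicates 1 and 3 of day 10. Without knockout replicates 1, 2, 3 and 4 of day 10 it was 845, 887, 1021 and 324.

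Genes called at day 5 were set against day 10. Of the 27 genes called at day 5, 25 were called at day 10 in the same direction, against 2.85 expected if the calls were independent, and 20 had the larger change at day 10. Hebp1, named after its values were seen, and Tfrc were the 2 not called at day 10. Across all genes the log2 changes of the 2 ages, which share no arrays, had a Pearson r of 0.467 and a Spearman rho of 0.342, where genes are not independent replicates. Of the 494 genes whose change differed between the ages, 178 had opposite signs at the 2 ages. All 27 genes called at day 5 kept their sign at day 10. None of the 178 was therefore called at day 5, and a reversal with age is not shown. At both ages Egln3, Ak4, Bnip3, Mif and Aldoa rose and Cabcoco1, Iigp1, Tmod4, Asb5 and the quinone reductase Nqo1 fell. Nqo1 fell by 0.42 at day 5 and by 0.85 at day 10.

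**Figure D3:**
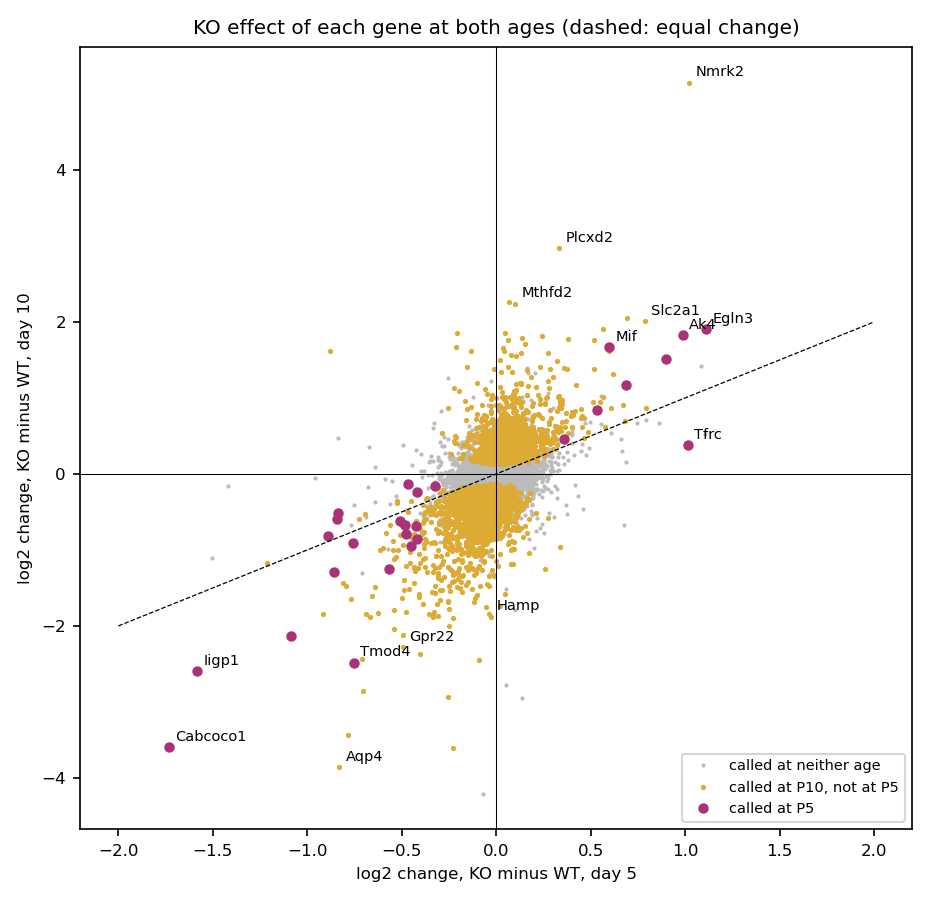
Log2 change, knockout minus wild type, of each gene at day 5 (x axis) and day 10 (y axis); genes called at day 5 are purple, those called at day 10 and not at day 5 yellow, others grey, and the dashed line marks equal change. Of the 27 genes called at day 5, 20 have the larger change at day 10, and Tfrc lies below the dashed line.

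**Figure D4:**
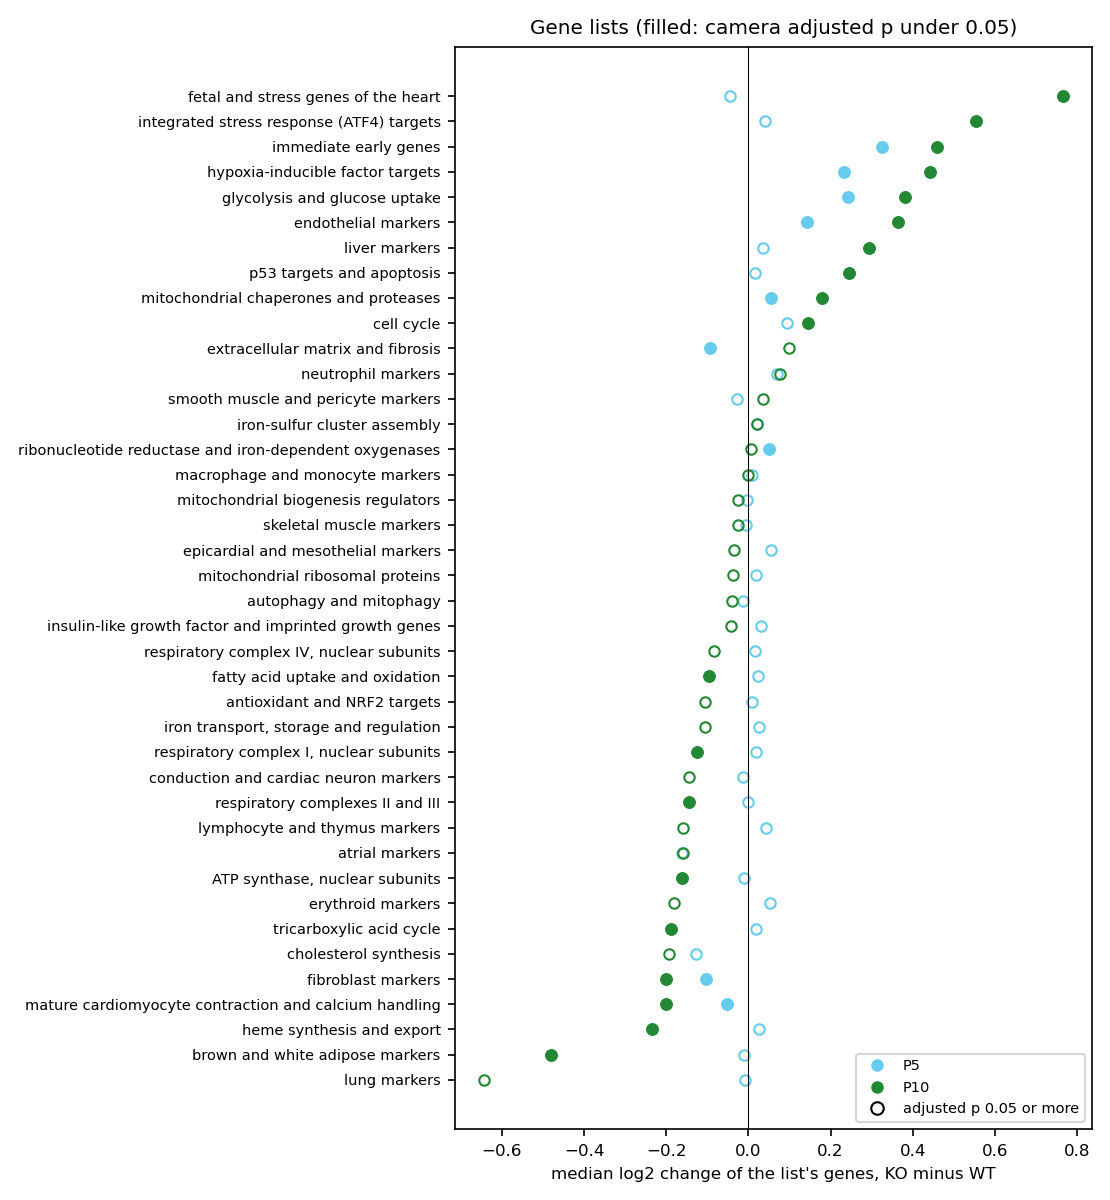
Median log2 change, knockout minus wild type, of each of the 40 gene lists at day 5 (blue) and day 10 (green); filled points passed camera at an adjusted p under 0.05 with the preset correlation. The integrated stress response has a median of 0.040 at day 5 and 0.56 at day 10.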

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

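The tests of RNA quality, of brown fat and of the share of cardiomyocytes given here were chosen after the results they bear on were seen, and the demand that the brown fat slope clear its bound with any 1 array left out was added after the slope was seen.

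The 8 day 5 arrays can be divided into 4 and 4 in 35 ways. The real division called 27 genes, 1 of 35 divisions gave as many (the real one), and the highest other gave 1. At day 10 the real division called 3753 genes, again 1 of 35 gave as many, and the highest other gave 154. A share of 1 of 35 is the smallest these divisions can give, so chance is made less likely at each age but not excluded. Any other difference that follows the same grouping would give the same counts. For the difference between ages, 4 of 100 drawn divisions gave 494 genes or more, the real one included, with the larger count taken over both signs, and the highest other gave 1992. The 3 others all kept the real grouping at day 10 and mixed the genotypes at day 5, and the highest division without it gave 7. Among the drawn divisions a count this high came with the real day 10 grouping whatever the day 5 grouping, a reading made after the counts were seen, so the divisions say nothing on whether the change differs between the ages.

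Knockout replicate 3 at day 10 stood apart. Its mean correlation with its group was 0.985, it measured 11.19 for Tfrc against 11.81 to 11.88 in the other 3, and it was far from them for Bex1 (10.91), Myc (7.41), Kcnj3 (2.18) and the mean of the iron-dependent oxygenase list (7.996). Lower RNA quality stays open: its beta-actin 3′ minus 5′ value of 1.39 lay near the top of the other 7 day 10 arrays, which reached 1.40, its Gapdh value of 0.483 lay under their highest of 0.510, and neither decides it. A larger size of the same knockout change stays open too: its deviation from a pair of other knockout arrays correlated across genes with the knockout change of the remaining array at a mean r of 0.147, between the bounds of 0.1 and 0.3 set beforehand, while knockout replicates 1, 2 and 4 gave -0.144, -0.274 and 0.221. A difference in the tissue taken may also have contributed and was not tested.

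The breadth of the day 10 change was weighed against less attached brown fat in the knockout samples. With the mean of 4 brown fat markers as a covariate, 757 of the 3753 genes stayed called and 3734 kept their sign. Their median absolute change went from 0.373 to 0.327 and the median SE from 0.0846 to 0.126, so the calls ended mainly through the larger SE of a covariate that differs by genotype. The slope of the adjusted on the unadjusted changes was 0.852, but 0.767 to 1.15 with 1 array left out, which crosses the bound of 0.8; a contribution of attached fat to part of the change cannot be told apart from the knockout effect here. The knockout effect named by the design stays open.

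The rise of endothelial markers at day 10 was weighed against a lower share of cardiomyocytes, which would raise markers of every other cell type alike. Fibroblast markers instead had a median of -0.20 and were called lower by camera, though with adjusted p = 0.276 with an estimated correlation, and macrophage markers a median of -0.0023, against 0.36 for endothelial markers. These values argue against a lower share of cardiomyocytes as the whole cause, provided that differences in attached tissue did not lower the fibroblast and macrophage markers. Whether they did was not tested. A change within the endothelial cells or in their number may remain, as a hypothesis, and attached tissue that brings its own vessels was not tested.

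Of 432 groups of 4 values examined, 27 held 1 array far from the other 3, where chance gives about 21.6; 6 of the 27 were knockout replicate 3 at day 10, given above. The others at day 5 were, in wild-type replicate 2, Bnip3 at 11.26, Ctf1 at 7.52, Junb at 6.85, Mthfd2 at 7.78 and the lymphocyte list mean at 5.33, in wild-type replicate 1 the extracellular matrix list mean at 10.72, and in wild-type replicate 4 Gapdh 3′ minus 5′ at 0.459. In the knockout they were Nqo1 at 7.84, Acta1 at 9.62 and the middle Tfrc control probe set at 7.56 in replicate 1, Mthfd2 at 7.69 in replicate 2, and Pdxp at 8.20 with the heme and mitochondrial chaperone list means at 9.16 and 10.30 in replicate 4. At day 10 wild-type replicate 3, the array with lung signal, was far from its group for Fbxl5 (8.26), Col8a1 (8.002), Dcn (12.49) and the iron and lymphocyte list means (7.94 and 5.06). Wild-type replicates 4 and 1 were so for the mitochondrial ribosomal (9.22) and iron-dependent oxygenase (8.01) list means.

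Limma's test of the difference between ages called 40 of the 95 genes named, on a log2 unit that may not be equal at both ages. These genes were chosen from the same data, some of them by this very difference, so the share is no result. Over all genes 494 of 18193 were called, 2.72%. Beyond the 5 largest positive and 5 largest negative differences, Nmrk2 (4.13), Plcxd2 (2.63), Acta1 (2.50), P3h2 (2.19), Mthfd2 (2.14), Aqp4 (-3.03), Lrtm1 (-1.96), Cabcoco1 (-1.86), Hamp (-1.85) and Gpr22 (-1.78), the change was more positive at day 10 for Col8a1 (2.06), Cdkn1a (1.65), Chac1 (1.56), Bex1 (1.40), Ccn1 (1.36), Myc (1.31), Slc2a1 (1.22), Pfkp (1.10), Mif (1.07), Trib3 (1.07), Ak4 (0.84), Atf4 (0.78), Gfer (0.75), Lonp1 (0.72), Aars (0.71), Bcl2 (0.69), Ero1a (0.51), Nubp1 (0.50) and Pdxp (0.49). It was more negative for Tmod4 (-1.73), Pla2g5 (-1.72), Ppara (-1.08), Asb5 (-1.05), Ctf1 (-0.68), Cat (-0.63), Pink1 (-0.59), Ryr2 (-0.57), Pln (-0.44), Nqo1 (-0.43) and Urod (-0.40).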

How the results depend on the processing

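The brown fat and airway covariates, the common SD, the pair of arrays left out and the lists on 8 arrays were chosen after seeing the data. Re-centring, quantile normalisation and cyclic loess across the 16 arrays gave 26 to 33 genes at day 5, 3654 to 3852 at day 10 and 459 to 526 for the difference between ages, against 27, 3753 and 494. The cause of the shifts that follow was not tested, with exceptions. Fewer arrays, a stricter threshold or a count of probe sets make some of them, and the brown fat covariate at day 10 was weighed above. Testing every probe set outside the controls gave 6519 calls at day 10, which are probe sets and not genes, so the count cannot be set beside 3753. Array weights, which were 0.114 for knockout replicate 3 at day 10 and 0.727 or more for the others, gave 155 calls at day 5 and 823 for the difference. The Y-linked mean as a covariate, which partly followed genotype at day 5, left 2 calls at day 5 and no call of Tfrc (1.13). The 8 arrays of 1 age gave 63 and 1570. Adjusted p under 0.01 gave 11, 1987 and 135 genes at day 5, at day 10 and for the difference, and a change of at least 1 gave 5, 254 and 82. The brown fat covariate gave 855 at day 10 and 41 for the difference. It reversed Scgb3a2 (0.55), not called then. Adipoq was 0.064 and not called, but it is itself part of that marker mean, so this value tests nothing. The airway covariate gave 249 for the difference. Without knockout and wild-type replicates 3 of day 10 the difference had 810 genes and Tfrc at day 10 was called (0.59). Each age scaled to a common SD gave 415. Leaving out 1 array gave 10 to 37 genes at day 5, 2957 to 4109 at day 10 and 246 to 1021 for the difference, the last without knockout replicate 3 at day 10; the Tfrc change was 0.92 to 1.20 at day 5 and 0.31 to 0.54 at day 10, where the highest value, without knockout replicate 3, was called. At day 5 the Tfrc call was lost when any 1 of 6 arrays was left out. Of the other Tfrc probe sets 1 was called higher at day 5 (0.63), 3 were not (1.08, 0.57 and 0.97), and the 5′ control probe set reversed the direction, -1.61 at day 5 and -0.46 at day 10. Lists past the threshold numbered 9, 19 and 16; an estimated correlation left 3, 1 and 1, fry 3, 18 and 4, and single arrays left out 6 to 14, 17 to 22 and 16 to 21, with 14 at day 5 without wild-type replicate 2. The tag-number block, with a correlation of 0.0422 in 7 clusters, gave 27, 3931 and 551 genes. The planned change from day 5 to day 10 in wild-type hearts was not run, since the ages were normalised apart. Replicate numbers follow accession order and were not used to pair animals, so the blocked fit was that by tag number. At day 10 the knockout and wild-type replicates 3 have neighbouring tag numbers, as do the replicates 4. The labels do not say whether these are littermates. Low signal limits what can be said of the 5′ Tfrc probe set at day 10, where the group means were 2.95 and 2.49. It also limits the size of the fall at day 5, where the knockout mean was 4.68.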

Other observations

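The genes Myl7, Lcn2 and Xist were chosen after their values were seen; the list tests were planned.

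Several lists held genes that moved at day 10 while camera called none of these lists but the fibroblast markers, a call lost with an estimated correlation (adjusted p = 0.276). Of 29 autophagy and mitophagy genes 5 rose and 6 fell (5 and 7 adjusted over the list alone; 2 and 3 with the 8 arrays; camera adjusted p = 0.351): Bnip3 rose by 1.51, while Pink1, the kinase that marks damaged mitochondria, fell by 0.71. Of 21 antioxidant and NRF2 target genes 2 rose and 5 fell (3 and 5 adjusted over the list alone; 1 and 3 with the 8 arrays; camera adjusted p = 0.110), catalase, Cat, by 0.62 and Nqo1 by 0.85. Of 58 mitochondrial ribosomal proteins 9 rose and 7 fell (the same counts adjusted over the list alone; 4 and 1 with the 8 arrays), where the median was -0.038 and the mean 0.012. In smooth muscle and pericyte markers 3 of 12 rose and 2 fell (the same counts adjusted over the list alone; 2 and 0 with the 8 arrays), the pericyte receptor Pdgfrb rising by 0.45 and Smtn falling by 0.50, with -0.29 without knockout replicate 3 and no call without wild-type replicate 3. Atrial markers had 3 of 11 lower (4 adjusted over the list alone, and 0 with the 8 arrays). Among them Kcnj3 fell by 2.004 to a knockout mean of 4.98, under the pooled 5.17 but near the day 10 median of 5.03. Its change was -1.07 without knockout replicate 3, and its call was lost without wild-type replicate 1 or 4. Fibroblast markers had 5 of 12 lower (6 adjusted over the list alone, and 1 with the 8 arrays), Gsn by 0.41 and Dcn by 0.26.

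Immune cell markers showed no call at day 10: 0 of 20 macrophage and monocyte genes, 0 of 9 neutrophil genes and 0 of 14 lymphocyte genes passed limma over all genes or adjusted over the list alone, in a comparison with 5962 genes at an unadjusted p under 0.05. The macrophage receptors Csf1r and Cx3cr1 measured -0.27 and -0.32 (limma adjusted p = 0.117 and 0.149), and Cx3cr1 -0.13 without knockout replicate 3. Cell cycle genes had 2 of 29 higher (0 adjusted over the list alone; 0 with the 8 arrays; camera adjusted p = 0.0334, and adjusted p = 0.724 with an estimated correlation).

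The lists not given elsewhere moved as follows at day 10, as genes higher and lower, then the same adjusted over the list alone. They were 6 and 2 of 22 (6 and 3) for extracellular matrix, 9 and 5 of 26 (9 and 6) for iron-dependent oxygenases, 2 and 4 of 15 (2 and 4) for complex IV, 0 and 4 of 16 (0 and 4) for cholesterol synthesis and 1 and 1 of 14 (1 and 1) for imprinted growth genes. Among markers they were 1 and 0 of 12 (1 and 0) for epicardium, 0 and 2 of 10 (0 and 2) for conduction, 0 and 2 of 10 (0 and 2) for erythroid cells, 0 and 2 of 13 (0 and 2) for skeletal muscle, 0 and 1 of 11 (0 and 0) for lung and 1 and 0 of 9 (3 and 0) for liver. With the 8 arrays limma called 2 and 2 for extracellular matrix, 4 and 2 for oxygenases, 1 and 0 for imprinted growth genes, 0 and 1 for conduction, 0 and 1 for skeletal muscle and 0 for the 6 others. Of these 11 lists camera called liver alone, with adjusted p = 0.5 with an estimated correlation.

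Some values bear on how the hearts were taken. The atrial light chain Myl7 measured 9.12 and 8.80 in wild-type replicates 1 and 2 at day 5, 6.14 to 6.71 in the other 6 day 5 arrays and 12.35 to 12.90 at day 10, on scales that differ between the ages. Lcn2 measured 7.24 in knockout replicate 3 at day 10 and 2.93 to 3.64 in the 7 other arrays of that age. The mean of the measured Y-linked genes lay between 7.26 and 8.51 and Xist between 4.11 and 6.75 over all 16 arrays. At day 5 the Y-linked mean was 8.04 to 8.23 in wild-type and 8.17 to 8.51 in knockout arrays, so as a covariate it partly followed genotype. At day 10 it was 7.26 to 7.65. Within neither age did it split the arrays into a high and a low set. Xist lay between 6.30 and 6.75 at day 5 and between 4.11 and 4.62 at day 10, again without such a split. These values argue against a mix of sexes within an age, and so against sex as the source of the day 5 calls lost with this covariate.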
